A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

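RNA of *Bradyrhizobium diazoefficiens* USDA 110, a soil bacterium that nodulates soybean, was compared on 2-colour expression arrays. Per the labels, cultures in arabinose-gluconate medium were kept under air for 24 h without shaking, with 20 µM P6 (labelled Pterocarpan 6; pterocarpans are a class of isoflavonoid compounds made by legumes) or with the solvent DMSO. The labels' protocols describe hot-phenol extraction, cDNA synthesis with random hexamers and labelling of the cDNA with Cy3 or Cy5. The 3 replicates are separate biological preparations according to the series' design text. Each replicate was hybridised to 2 arrays, 1 with P6 in Cy5 and DMSO in Cy3 and 1 with the dyes exchanged, which makes 6 arrays.

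The deposited values are log ratios of both channels, 1 per feature and array, read here as log2, which were near 0 on average: the array medians lay between 0.01 and 0.06. The scanner, the background correction, the normalization method and the rule behind the empty cells are not given in the sources used here. The log base is not stated either. Base 10 was set aside because the highest value, 7.27, would then be an 18573200-fold ratio, beyond the range of a 16-bit scanner. Base 2 was assumed, as is usual for such arrays, and natural logs, under which every log2 ratio would be 1.44 times as large, are not excluded. The direction of the ratio is not stated. All 15 pairs of arrays correlated positively across features although the labels give the swapped arrays the opposite dyes, so the swapped arrays had been turned before deposit. P6 over DMSO is the likely direction. Its basis is that the labels call P6 the treatment and DMSO the control, and that the unswapped arrays hold P6 in Cy5, the usual numerator.

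A gene-wise dye correction was also found in the values. In all 2980 features with values on all 6 arrays, the mean of the 3 arrays with P6 in Cy5 equalled the mean of the 3 arrays with P6 in Cy3 within 1e-06, and this held for 0 of the 5155 other features with values in both orientations. The planned test for a dye effect per feature was therefore void and was not run. Such a correction cancels in the mean of an array and its dye swap, so it does not move the replicate means of complete features, but it can move those of features with empty cells.

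Empty cells numbered 5275 and 4926 of 8480 on the arrays of replicate 1, 4236 and 2928 on those of replicate 2, and 169 and 240 on those of replicate 3. A feature was tested where each of the 3 replicates had a value on at least 1 array, which left 3709 features (43.7%). The test therefore leaves out most features with empty cells in replicates 1 and 2. Signal intensities were not analysed here, so the brightness behind each ratio is unknown, and the number of arrays limits the precision.

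The arrays of each replicate were averaged, and the 3 replicate means were fitted in limma 3.58.1 (R 4.3.3) with an intercept tested against 0 in a 2-sided test, with empirical Bayes moderation (prior degrees of freedom 5.18) and Benjamini-Hochberg adjustment over all tested features. A feature counted as higher or lower at an adjusted p under 0.05. No values were identical between an array and its dye swap, and the SD of their differences was 0.207, 0.267 and 0.330 in replicates 1, 2 and 3. The pipeline was tested on simulated data for this comparison with 3709 features, 20 runs and 200 changed features per run. It recovered 86.4% of features changed by 1 on the log2 scale and 10.2% of those changed by 0.5, with 4.87% false calls. The data gave 1509 calls, far more than the 200 simulated changes, which makes the adjusted threshold looser in the data. The recovered percentages therefore do not describe the sensitivity of the real comparison. The list test called 4 of 100 unchanged simulated lists and 100 of 100 lists shifted by 0.5. The simulated genes were drawn independently, so these counts do not show how the list test behaves where members vary together.

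Before the data were examined, the fit, its alternatives, 29 gene lists and the rule for named genes were fixed. Each list was tested with camera in limma, with a preset correlation of 0.01 between genes, where at least 3 members were tested, and with an estimated correlation and with fry as alternatives. Named genes were the 12 highest and 12 lowest ratios past the test with 1 sign in all replicates, up to 4 members per list with the largest ratios past the test or else the member with the smallest p, and 8 loci of flavonoid-inducible efflux and nodulation where measured. Other alternatives were array centring, scaling and quantile normalization, either dye orientation alone, a fit of all 6 arrays with the replicate as a block and a dye term, stricter and looser rules on empty cells, other variance moderation, stricter thresholds, means over probes of 1 gene, and each replicate left out.

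Features were named from a platform annotation table, which is old. It listed 8462 of 8480 features, each with a single name, of which 1469 were a gene symbol and the others a locus tag. The 18 features outside the table are unnamed here. The current gene table of the species shared no identifiers with it, so no products, coordinates or updated names are given. The lists therefore rest on symbols and locus tags. No feature could be placed in the lists of cytochrome P450, ABC transporters, TetR-type regulators and transposases, which rely on product names. Different probes of a gene were kept as separate features. Figures were drawn with matplotlib 3.10.9.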

Results

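Transcript ratios between cells given 20 µM P6 and cells given DMSO were measured after 24 h in *B. diazoefficiens* USDA 110, in 3 biological replicates with a dye swap each. The arrays held 8480 features, of which 3205 to 8311 had a value on any 1 array. The series title names the comparison of P6 with its solvent, so the question was which transcripts differed between the treated and the control cells. Ratios across features correlated at r = 0.845 to 0.954 between an array and its dye swap. The dye correction found in the values had made the orientation means of complete features equal, so part of this agreement was imposed by it. The replicate means of tested features correlated at 0.873 between replicates 1 and 2, 0.841 between replicates 2 and 3 and 0.697 between replicates 1 and 3. These are correlations across genes, which are not independent replicates.

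A few transcripts differed by large factors between P6 and DMSO, in either direction. The locus bll7025 rose 81.6-fold (41.6-fold after quantile normalization and 131.5-fold without replicate 3), and fixK (bll2757), which codes for a regulator of genes used at low oxygen, rose 8.37-fold. The loci bll5155, blr2887 and blr2455 fell 26.1-fold, 19.7-fold and 17.6-fold, and metF (bll1419), which codes for a methylenetetrahydrofolate reductase, fell 5.52-fold. Of 36 tested ribosomal protein genes 25 fell and of 7 tested sigma factors and general stress regulators 5 fell. Of 15 tested nitrogen fixation (nif and fix) features 9 rose, most of them fix genes. All directions are P6 over DMSO, the likely but unstated direction of the deposited ratios. With the sign turned, each increase named here would be a decrease and each decrease an increase.

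Of 3709 tested features, 679 rose and 830 fell with P6 at an adjusted p under 0.05 (limma, Benjamini-Hochberg), together 40.7%. With the sign turned, 830 would be higher and 679 lower. Among these calls, 131 rose and 224 fell by at least 1 on the log2 scale, and 18 rose and 24 fell by at least 2. The sign was the same in all 3 replicates for 1502 of the 1509 calls. The median ratio of all tested features was 0.01. The count fell to 798 without replicate 2, of which 779 were among the 1509, and to 2 (bll0524 and bll3711) without limma's pooling of variances across features, where 1179 features had an unadjusted p under 0.05. A call reported below as lost without replicate 2 shares in this general fall, and the loss alone does not set that gene apart.

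The highest ratio, that of bll7025, was 6.35 ± 0.39 on the log2 scale (SE, n = 3, limma adjusted p = 0.000131), with 7.27, 6.81 and 4.97 in replicates 1, 2 and 3. In replicates 1 and 2 it had a value only on the array with P6 in Cy5, so these ratios can have been moved by the dye correction, and replicate 3, with both dyes, gave 31.4-fold. The next were blr0497 with 3.57 ± 0.39 (2.98 without replicate 1 and 4.20 without replicate 3), bll2471 with 3.28 ± 0.26, bll0174 with 3.22 ± 0.19 and fixK (bll2757) with 3.06 ± 0.14 (SE, n = 3). The neighbouring locus of fixK, bll2758, rose by 2.19 ± 0.30. The other loci of the highest 12 were blr2308 (2.98), bsr6520 (2.77), bll4927 (2.65), bsr6686 (2.25), bll7551 (2.23, or 2.85 without replicate 3) and blr5790 (2.19). Replicate 3 gave the smallest of the 3 ratios for each of these 12 features.

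The lowest ratio, that of bll5155, was -4.71 ± 0.15 (SE, n = 3, limma adjusted p = 2.78e-05), with -5.01, -4.38 and -4.73 in replicates 1, 2 and 3. The loci blr2887 and blr2455 followed with -4.30 ± 0.28 and -4.14 ± 0.19. A feature of blr0857 stood at -3.46 ± 0.21, but the 3 probes of that gene differed: another fell by only 0.69 and the remaining probe had a ratio of 0.23 that did not pass (limma adjusted p = 0.204). The other features of the lowest 12 were bsl4407 (-2.84), blr5502 (-2.83), bll7395 (-2.65), bsr7643 (-2.63), bll2363 (-2.48), metF (-2.46), blr6774 (-2.40) and blr5264 (-2.37). The gene tables used here give no product for the features named by locus tag alone.

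**Figure D1:**
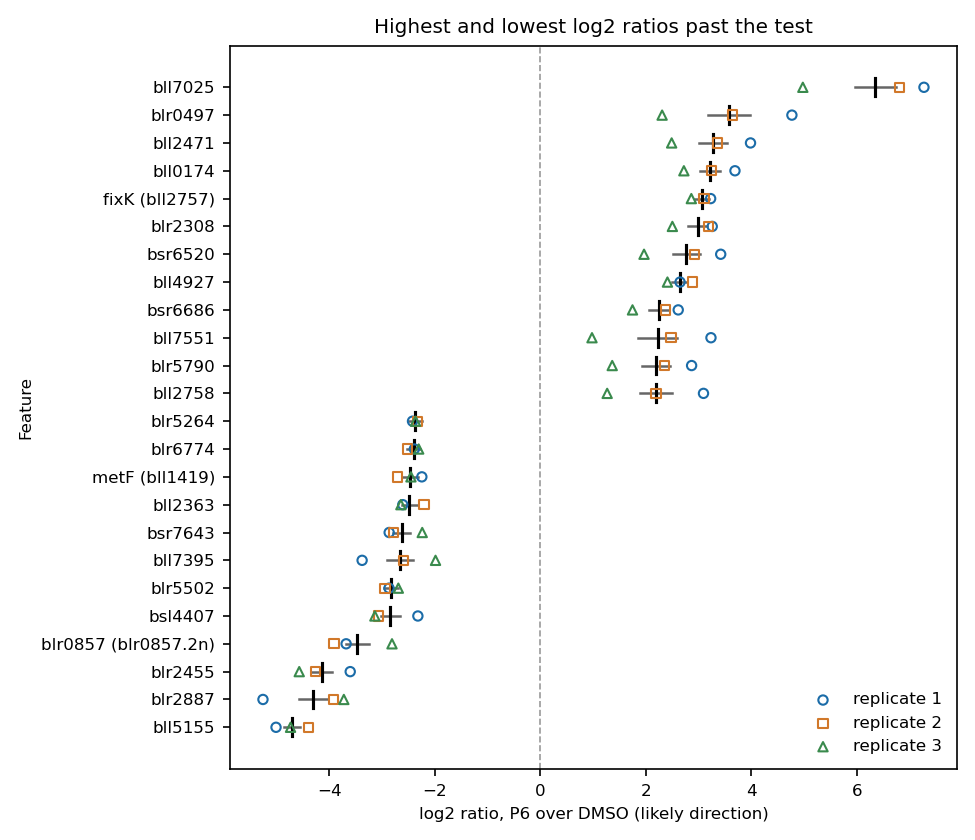
The 12 highest and 12 lowest log2 ratios of P6 over DMSO past the test, in the likely direction. Symbols are replicate means, black ticks the mean of 3 replicates and grey lines ± 1 SE; the means run from 6.35 for bll7025 to -4.71 for bll5155, and each feature has the same sign in all 3 replicates.

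Ribosomal protein genes were lower with P6. Of 36 tested members, 25 fell, 2 rose and 9 did not pass, with a median log2 ratio of -0.70 (limma camera, Benjamini-Hochberg adjusted p = 3.03e-05). The counts adjusted over the list alone were the same. With an estimated correlation camera gave an adjusted p = 0.909, but that setting has too few residual degrees of freedom to decide, here and for the lists below. The small-subunit gene rpsU (bsr7117) had the lowest ratio of the list, -1.34 ± 0.13, followed by rpmG (bsr5117) with -1.29 ± 0.18, rpsM (bll5378) with -1.07 ± 0.14 and rplU (blr0420) with -1.05 ± 0.12 (SE, n = 3). The 2 members that rose were rplR (bll5384, 0.79) and rpsP (blr0482, 0.44), named after their values were seen. Among the 6 tested features of the tRNA ligase list, cysS (blr3790, 0.61) and alaS (bll5750, 0.55) rose and thrS (blr5537, -0.74) fell. Each of these 3 calls was lost without replicate 2, with limma adjusted p = 0.0721, 0.141 and 0.0914. That of cysS was also lost without replicate 1 (adjusted p = 0.0715) and that of alaS without replicate 3 (0.0508). The list passed fry (adjusted p = 0.0385) but not camera (adjusted p = 0.571).

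Tested sigma factors and general stress regulators were also lower. Of 7 tested members, 5 fell and none rose, with a median of -1.16 (limma camera, adjusted p = 0.0129). Adjusted over the list alone, the counts were again 5 and 0, and with an estimated correlation the adjusted p = 0.909. The 4 untested members had values in replicate 3, of which 3 were above 0 on both arrays and 0 below. The lowest were bsr7796 with -1.79 ± 0.13 and bll7795 with -1.76 ± 0.13. With blr7797 at -1.16 ± 0.17 they form the adjacent loci that were listed beforehand, from background knowledge and not from the probe table, as the regulator locus of the general stress response. Of the 2 tested sigma-54 genes, rpoN2 (blr0723) fell by 1.44 ± 0.15, while rpoN1 (blr1883.1n) had a ratio of 0.13 that did not pass (limma adjusted p = 0.465). The gene of the main sigma factor, sigA, fell by 0.66. Among 26 tested chaperones, small heat-shock proteins and proteases 3 rose and 4 fell, against 2 and 0 adjusted over the list alone. Without replicate 2, 1 of the 3 increases and 0 of the 4 decreases were kept, with clpS (bll2636) lost at a limma adjusted p = 0.0721, and without replicate 3 all 3 increases and 1 decrease were kept. Their median was -0.25 with 17 ratios below 0, and in replicate 3 the list had 21 members below 0 on both arrays and 7 above. The small heat-shock gene hspH (bll0729) rose by 1.18 ± 0.25 (SE, n = 3), while another feature annotated hspH (blr6571) had a ratio of -0.31 that did not pass. The ratios of lon and dnaJ (blr2626), 0.74 and -0.85, passed narrowly, and dnaJ had -1.31, -1.36 and 0.12 in replicates 1, 2 and 3. Both calls were lost without replicate 2 (limma adjusted p = 0.286 and 0.0904), that of dnaJ also without replicate 1 (0.0505), and each in 4 further settings (0.0528 to 0.0620 for lon and 0.0529 to 0.0810 for dnaJ). The list did not pass camera (adjusted p = 0.642).

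Tested features of nitrogen fixation were higher as a list. Of 38 nif and fix features 15 were tested, of which 9 rose and none fell, with a median of 0.48 (limma camera, adjusted p = 0.000441). The counts adjusted over the list alone were also 9 and 0, 5 members passed without replicate 2, and with an estimated correlation the adjusted p = 0.909. Besides fixK (bll2757), nifN (blr1746), which codes for a scaffold protein of nitrogenase cofactor assembly, rose by 2.04 ± 0.29, another feature annotated fixK (bll6061) by 1.16 ± 0.13 and fixQ (bsr2765), a gene of the high-affinity terminal oxidase, by 1.02 ± 0.23 (SE, n = 3). Most of the 9 were fix genes. Of the tested nif genes only nifN passed. The ratio of nifS (blr1756) was 0.35 (limma adjusted p = 0.0726) and that of the nitrogenase subunit gene nifK (blr1744) was -0.26. Of 5 tested denitrification genes, napE (bsr7036, 0.56) and nosL (blr0319, 0.47) rose, 3 passed adjusted over the list alone, and neither napE nor nosL passed without replicate 2 (limma adjusted p = 0.0681 and 0.228) or without replicate 1 (0.174 and 0.0858). Among 15 tested genes of carbon dioxide fixation and uptake hydrogenase, 5 rose and 1 fell, with increases of hypA (blr1730) by 0.97 ± 0.13, hupC (blr1722) by 0.92 ± 0.13 and hupN (bll6910) by 0.70 ± 0.13. Another feature annotated hupN (bll6949) had a ratio of 0.18 that did not pass. Of these 6 hydrogenase and fixation calls, 3 of the increases and not the decrease were kept without replicate 2. Neither of these lists passed camera (adjusted p = 0.491 for both).

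**Figure D2:**
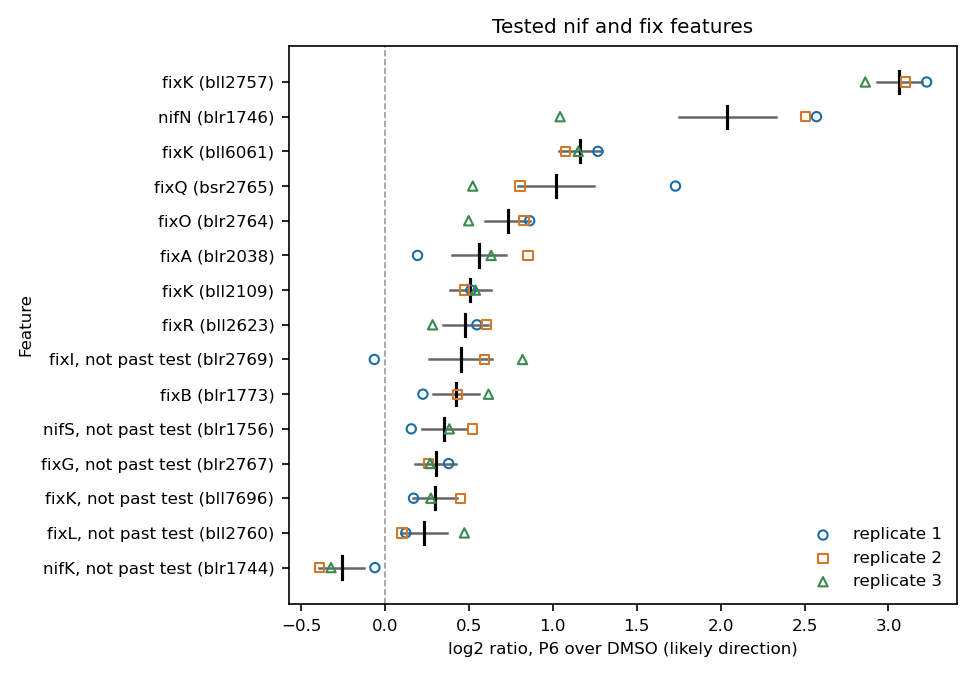
Log2 ratios of P6 over DMSO, in the likely direction, of the 15 tested nif and fix features. Symbols are replicate means, black ticks the mean of 3 replicates and grey lines ± 1 SE; 9 features rose, from 0.42 for fixB to 3.06 for fixK (bll2757), and nifK was the only one with a mean below 0.

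Nodulation genes and the loci known for flavonoid-inducible efflux, listed because flavonoids of the host act on both, were mostly outside the test. Of 31 nodulation features 5 were tested, and nodI (blr0906), a gene of Nod factor export, rose by 0.65 ± 0.13 (SE, n = 3), a call lost without replicate 2 (0.60, limma adjusted p = 0.0852). Without replicate 1, 3 of the 5 rose. On both arrays of replicate 3, where 30 nodulation features had values, 21 were above 0 and 3 below, against 45.4% above and 34.9% below among all 8112 features with both values. Of the 25 untested ones among them 17 were above and 2 below, against 49.5% and 25.3% of all untested features, a difference that was not tested. Of the efflux loci, 3 were tested and none passed: bll7020 had a ratio of 0.43, bll4321 of -0.31 and bll7019 of 0.14 (limma adjusted p = 0.0658, 0.104 and 0.378). The locus bll7020 passed without replicate 3 (0.58, limma adjusted p = 0.0371) and with arrays centred on features with values on all 6 (0.44, adjusted p = 0.0484), a setting added after the data were seen. Neither list passed camera (adjusted p = 0.491 for nodulation and 0.896 for the efflux loci). Values of bll7021 were 0.30, 0.51, 0.35 and 0.54 on the 4 arrays of replicates 2 and 3, and those of bll4320 were 0.32, 0.46, 0.40 and 0.13. In replicate 3 alone, nodD1 (bll2023) had 0.40 and 0.28, nodC (blr2027) 0.23 and 0.58, and bll4319 0.08 and 0.36. In the multidrug efflux list, with 2 members tested, emrA (bll6622) rose by 0.98 ± 0.18. None of the 10 features of type III secretion was tested, and in replicate 3 their 9 pairs of values were above 0 on both arrays for 5 and below for 2.

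Genes of respiration and central metabolism moved both ways. Among 18 tested cytochrome and terminal oxidase genes 5 rose and 4 fell, with cycA (blr7544) at -1.15 ± 0.14, cycC (bll5913) at -1.11 ± 0.15 and coxB (blr1170) at -0.86 ± 0.12 (SE, n = 3). All 4 decreases were kept without any 1 replicate, and 3 of the increases without replicate 1 or without replicate 2. The ratio of coxN (bll3784) was 1.13 ± 0.13, and its call was lost in the fit of all 6 arrays with a replicate block and a dye term, where the ratio was the same (limma adjusted p = 0.0731). In the TCA cycle and glyoxylate list 4 of 10 tested members rose and 1 fell. The malate synthase gene glcB (bll1474) fell by 1.42 ± 0.14, while sucC (bll0455) and fumC (blr6519) rose by 0.86 and 0.85. The increases of this list also include gltD (blr7744, 0.98), a glutamate synthase gene by its symbol and not one of the TCA cycle. It is counted in the amino acid synthesis list as well. In the list of polyhydroxybutyrate and trehalose genes 2 of 5 tested members rose, phbC (bll6073) by 0.84 ± 0.16 and phbA (blr3724) by 0.83 ± 0.13, while phbB (bll0225) and another feature annotated phbC (blr3732) had ratios of 0.13 and 0.11 that did not pass. The trehalose gene otsA (bll0322) fell by 0.45, a call lost without replicate 2 (limma adjusted p = 0.241), without replicate 3 (0.0544), with P6 in Cy3 only (0.0562) and in the fit of all 6 arrays with a replicate block and a dye term (0.0857). Of 8 genes of NADH dehydrogenase and ATP synthase, atpH (bll0443) alone passed, with 0.90 ± 0.15. In the amino acid synthesis list 9 of 41 tested members rose and 8 fell, among them ilvD (bll4763) at 0.93 ± 0.13 and cysK (bll4682), a gene of cysteine synthesis, at -1.31 ± 0.18, beside metF. Another feature annotated cysK (bll4453) had a ratio of 0.09 that did not pass. The increases also include metG (bll4516, 0.91), by its symbol a tRNA ligase gene that was placed in this list and not in that of tRNA ligases. Of these amino acid calls 5 increases and 3 decreases were kept without replicate 2, and 5 and 7 without replicate 3. None of these lists passed camera (limma, adjusted p = 0.571 or higher).

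None of the envelope, lipid, motility, aromatic degradation, iron and peroxide defence lists passed camera (limma, adjusted p = 0.602 or higher). Of 18 envelope genes 4 rose and 3 fell, with rfaF (blr5929) at 0.88 ± 0.15, exoN (blr1499) at -0.79 ± 0.13 and lpxC (bll6595) at -0.64 ± 0.15 (SE, n = 3). Only 1 of the 4 envelope increases was kept without replicate 2 or without replicate 3, while 2 and 3 of the decreases were kept. The call of murG (bll6602) was lost without replicate 2 (limma adjusted p = 0.0708) and narrowly without replicate 3. In fatty acid synthesis 2 of 14 rose and 3 fell, with the acyl carrier protein gene acpP (bsr4084) at -1.12 ± 0.18. Both increases were lost without replicate 2, accA (blr0191) with limma adjusted p = 0.0616 and acpD (blr5106) with 0.125, and that of accA also without replicate 3 (0.0694), and 2 of the 3 decreases were kept in each case. In fatty acid degradation 1 of 6 rose, fadB (bll2946) with 0.73, and 2 fell. Those were fadD (bll1319) at -1.06 ± 0.13 and another feature annotated fadB (bll3036) at -0.58. The call of bll3036 was lost without replicate 2 (limma adjusted p = 0.0822). The remaining features, all annotated fadB, had ratios of 0.30, 0.29 and -0.27 that did not pass. In the flagellum list 2 of 13 rose and 3 fell, and the 2 probes annotated flaA disagreed, with -1.37 for blr3695.1n and 0.48 for blr3695, the latter call being lost without replicate 2 (0.37, limma adjusted p = 0.329). The other flagellar increase, flgH (blr5830), was lost without replicate 1, 2 or 3 (0.0715, 0.141 and 0.0659), and without replicate 2 only 1 of the 3 decreases was kept, with fliF (blr6999) lost at 0.188. In chemotaxis 1 of 5 passed, cheA (blr2192) with -0.53, which was lost without replicate 2 (limma adjusted p = 0.0616) and without replicate 3 (0.0755). In aromatic compound degradation 2 of 12 rose and 1 fell, and each of the 3 calls was lost in some setting. Those of paaK (blr2897) and paaB (bsr2892) were lost without replicate 2 (limma adjusted p = 0.109 and 0.303), and that of paaB also without replicate 3 (0.0800) and with P6 in Cy3 only (0.0776). The largest ratio of the list was that of pcaC (bll1385) with 1.30 ± 0.24, and this call was lost at the same ratio in the fit with a replicate block and a dye term (limma adjusted p = 0.156) and with P6 in Cy3 only (0.0645). None of 6 peroxide and superoxide genes passed, with sodF (bll7774) at 0.83 (limma adjusted p = 0.0525), which passed without replicate 1 (1.13, adjusted p = 0.000899) and in 4 other settings (adjusted p = 0.0280 to 0.0492). None of 4 iron genes passed, with bfr (bll6680) at -0.28 (limma adjusted p = 0.195), which passed without replicate 1 (-0.48, adjusted p = 0.0360). The 2 tested glutathione S-transferase genes moved apart, bll2509 with -0.70 and blr2503 with 0.39, and their calls were lost without replicate 3 (limma adjusted p = 0.0695 and 0.0925), that of blr2503 also without replicate 1 (0.0996) or 2 (0.221), with a replicate block and a dye term (0.115) and in 5 other settings (0.0502 to 0.144).

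Adjusted over the list alone, the flagellum list had 2 that rose and 4 that fell and the chemotaxis list had none. The other lists described in the preceding paragraphs kept their counts unless stated. In 4 lists the measures differed in sign. The median and the mean were 0.13 and -0.04 for chemotaxis, -0.08 and 0.05 for peroxide defence, 0.01 and -0.02 for amino acid synthesis and 0.01 and -0.10 for fatty acid degradation, and camera read amino acid synthesis as up and the other 3 as down. Of the 22 lists tested, 3 passed camera, 0 passed with an estimated correlation and 4 passed fry, which are those 3 and the tRNA ligases. The estimated correlations were -0.05 for nitrogen fixation, 0.06 for sigma factors and 0.11 for ribosomal proteins. For nitrogen fixation a correlation below 0 cannot account for the lost pass. With an estimated correlation, camera takes its p-values from the few residual degrees of freedom of 3 replicates, so a list could hardly pass after adjustment over 22 lists. The lost passes therefore do not decide whether the list results hold.

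**Figure D3:**
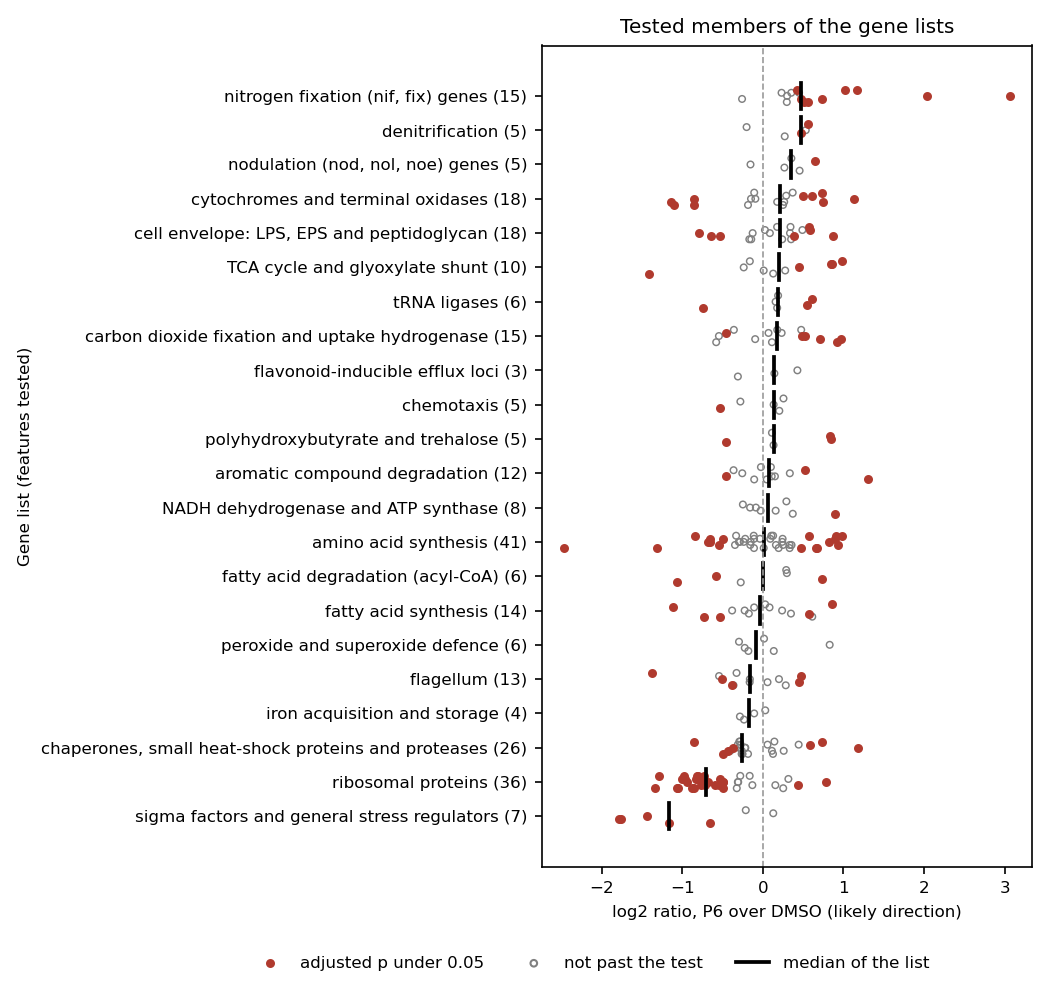
Log2 ratios of P6 over DMSO, in the likely direction, of the tested members of 22 gene lists, ordered by list median (black ticks). Filled points passed the test and open points did not; the medians run from -1.16 for sigma factors and general stress regulators to 0.48 for nitrogen fixation genes.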

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

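The comparison with short genes, that with other abundant transcripts and that of replicate 3 with replicate 1 on the negative side were tests chosen after the results were seen. Each of 80 values measured on all 6 arrays, 77 named features and 3 array measures, was searched for an array lying far from the other 5. None was found, where chance alone would give about 4. The arrays come in dye-swap pairs of the same RNA, which leaves little room for a single array to stand apart.

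The count of 1509 features past the test was set against the other sign patterns of the 3 replicates. Of the 4 patterns 1, the real one, gave as many, and the highest of the others gave 0. A share under 0.05 cannot be reached with 4 patterns.

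The lower ribosomal protein genes were weighed against 3 technical explanations. That features with values on all 6 arrays run low as a class was argued against, since the median of 31 complete ribosomal features was -0.77 while 98% of 10000 random lists of complete features had medians between -0.34 and 0.30. A trend in which abundant transcripts read lower stays open: 10 other transcripts taken to be abundant from background knowledge had a median of -0.0772 (bootstrap 95% interval -0.34 to 0.26), but no signal was measured for them here. Short genes fell more often, but ribosomal genes with tags of longer genes had a median of -0.54 (98% of random lists of such features lay between -0.29 and 0.29) and those with short-gene tags -0.82 (between -0.69 and 0.40). All these random lists held single features, while many ribosomal genes are neighbours that may vary together, so the ranges may be too narrow. The margin is smallest for the short-gene tags. An effect of P6 on these mRNAs may stand beside the trend with abundance as an untested explanation, with the sign of the ratio still only likely.

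In the 12 highest features replicate 3 gave the smallest ratio, which could come from a weaker response or from a higher background in that replicate. Features picked on replicate 2 alone, at 1 or more on the log2 scale, did not show it clearly, with a quotient of medians (replicate 3 over replicate 1) of 0.926 (bootstrap 95% interval 0.805 to 1.14). A weaker response in both directions was argued against by the negative side, where the quotient was 1.30 (1.24 to 1.41, 255 features). More background at low signal stays open, since the quotient of features with an empty cell lay lower than that of complete ones by a difference of -0.478 with an interval from -0.728 to 0.332 over only 12 features. No biological explanation of this difference between replicates was tested.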

How the results depend on the processing

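The centring on features complete on all arrays and the list test among those features were chosen after seeing the data, as were the counts of list calls kept without a replicate. Under centring, scaling, quantile normalization, robust moderation, either rule on empty cells and means over probes, the total lay between 1398 and 1652. With P6 in Cy3 only 421 features rose (cause not tested), but the ratios of complete features cannot differ between the dye orientations, whose means had been made equal. Stricter thresholds gave 285, 478 and 763 (higher, lower, total) at an adjusted p under 0.01 and 131 and 224 at a log2 ratio of at least 1. Without moderation 1 rose and 1 fell, 2 in all, both changed by at least 1, since 3 values leave few degrees of freedom. With 1 replicate left out, 294 to 737 rose, 504 to 885 fell and 798 to 1622 did either. The counts were lowest without replicate 2, which leaves replicates 1 and 3, the pair with the lowest correlation (0.697). No cause beyond this was tested. Read as natural logs, 799 calls reach 1, by the change of scale. With an estimated correlation 0 lists passed, a setting with too few residual degrees of freedom to decide. The mean correlation of replicate means was 0.804, and 0.291 with called features left out. Features are called where their replicates go together, so leaving them out lowers this correlation by selection. With the replicate as a block and a dye term, changed together (within-replicate correlation 0.657), 1480 features passed, 1391 of them shared.

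Of the 85 named features past the test, all lost it without moderation and 26 under some other setting, 22 of them without replicate 2. Those with the 12 highest and 12 lowest ratios lost it without moderation and in no other setting that gave them a value. The 4 with empty cells (bll7025, bll2471, bll7551 and blr5790) had none with P6 in Cy3 only or with all 6 arrays required, and the probe of blr0857 none in the mean over probes. Averaging the probes of flaA turned blr3695 to -0.45. List means near 0 changed sign, none past the test. With 1 replicate left out they were -0.0869 to 0.0284 (chemotaxis), -0.000126 to 0.0717 (cytochromes), -0.0920 to 0.210 (peroxide defence), -0.119 to 0.00458 (chaperones) and -0.0729 to 0.0226 (fatty acid synthesis). With P6 in Cy5 only, amino acid synthesis was at 0.0195; with P6 in Cy3 only, cytochromes were at -0.00758 and fatty acid degradation at 0.0925; among complete features, cytochromes were at -0.0411 and amino acid synthesis at 0.0275. The cause was not tested. The dye effect alternatives were not run because that test was void. Signal over background is not in the values, so what low signals limit is unknown.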

Other observations

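All tests in this part except the one on neighbouring genes were chosen after the results were seen, and the loci named here, other than those of the report, were picked by their values. Some changed genes lay in runs along the locus numbers, and how many such runs chance would give was not tested. The longest run past the test at 1 or more on the log2 scale held 6 features from bsl2596 to bsl2602, with ratios from -1.55 to -1.07. Other lower runs of 3 were bsr1472 to glcB (bll1474, mean -1.54), blr4223 to blr4226 (-1.32), bll6165 to bll6168 (-1.19), bll7046 to bsr7049 (-1.51) and the general stress loci bll7795 to blr7797 (-1.57), and 1 run was higher, blr5788 to blr5792 (mean 1.60). Beside bll7025, the untested locus bll7024 had 1.83 and 2.05 on the arrays of replicate 3.

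Short genes, tagged bsl or bsr, were over-represented among lowered features. With ribosomal proteins left out, 118 of 410 short genes (28.8%) and 687 of 3263 others (21.1%) fell (Fisher's exact test, 2-sided, p = 0.000604, across genes, which are not independent replicates). Among features outside the test that had both values in replicate 3, 6 of 4413 were at 1 or above on both arrays and 21 at -1 or below. The highest was phnL (blr1226) with 1.86 and 3.69, and the lowest was blr3677 with -2.81 and -2.83. Features outside the test were above 0 on both arrays more often (49.5%) than tested ones (40.4%). In 6 of 52 genes with several tested probes, probes passed the test in opposite directions, flaA and bsl2182 (0.45 and -1.51) among them.

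The 8.37-fold rise of fixK (bll2757) raised the hypothesis that the operons fixNOQP and fixGHIS, which the regulator encoded by bll2757 is known to activate, rose too. In replicate 3, where all 8 genes had values, their median was 0.45 (0.15 to 0.82), at the 99.6 percentile of 10000 random lists of 8 features and the 99.2 percentile of 10000 lists of 2 runs of 4 neighbouring features, and fixO (0.73) and fixQ (1.02) passed the test over 3 replicates while fixG (0.30) and fixI (0.45) did not. The test over 3 replicates thus shows a rise of fixO and fixQ. Whether the 8 targets rose as a set stays open, since the percentiles rest on 1 replicate and fixG and fixI did not pass. A rise of the same size as that of fixK was argued against, since fixK stood at 3.23, 3.10 and 2.86 in replicates 1, 2 and 3 and the median of the 4 tested targets at 0.62, 0.70 and 0.51. In *B. diazoefficiens* the FixK protein is also controlled after transcription, which these arrays do not measure.

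Neighbouring genes were examined for a shared direction. Of 191 pairs of adjacent locus numbers on the same strand with both genes past the test, 74.3% shared a direction, above the highest of 1000 shuffles (62.3%). That share was also above the 62.5% of 144 pairs on opposite strands (Fisher's exact test, 2-sided, p = 0.0232, across pairs that can share a gene and are not independent). This is consistent with co-transcription of neighbours, and the share of pairs on opposite strands leaves room for other regional causes, such as the place of the spots on the array, which was not tested.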
